A study of Homo sapiens with 8 samples.

How the data were processed

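The series holds 8 RNA sequencing libraries from U251 cells, 2 from each of 4 groups: KO1 control, KO1 with temozolomide (TMZ), KO2 control and KO2 with TMZ. The labels give Ribo-Zero depletion of ribosomal RNA, sequencing on an Illumina HiSeq, a TMZ dose of 1 mM and a treatment of 72 h. Libraries were grouped by the line and the treatment in their titles. The values are deposited gene counts: whole numbers per gene symbol, 1 file per library, not normalised. The submitters' processing notes name the genome build hg19 and the tools HISAT2 2.1.0, HTSeq 0.9.1 and DESeq2 1.18.1, without saying what each did. The annotation and the strand setting are not given in the sources used here, so genes that overlap on opposite strands may share counts. The same caution holds for histones, ribosomal proteins with pseudogenes, mitochondrial genes with nuclear copies, AKR1C1 with AKR1C3, and other near-identical paralogs. The labels also mention capture Hi-C, which was not analysed here.

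The counts hold 56648 gene names. Reads given to no gene were kept out of library sizes and tests. Between 57.6% and 60.1% of the reads counted were assigned to a gene, and 10.6% to 11.8% were ambiguous between genes. Names, gene order on chromosome 10 and gene lengths came from GENCODE 29 and RefSeq GRCh38.p14. Those references differ in build from the counts, so no coordinates were used. Of the 15850 genes tested, 14135 had a symbol in the reference. The genes left out failed the edgeR filter on low counts, filterByExpr with the 4 groups.

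Fold changes were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors, a model with 1 mean per group and the quasi-likelihood F-test with 4 residual degrees of freedom. The 5 comparisons were the TMZ effect averaged over the lines, the TMZ effect in KO1, the TMZ effect in KO2, the difference of these effects, and KO2 against KO1 in control cells. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The standard error of a log2 fold change was approximated as its absolute value divided by the square root of F. Where a group held few counts, this value can fall below the counting error. Levels are TMM-normalised CPM. Principal components used log2 CPM with a prior count of 2.

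Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and at least 3 tested members, adjusted over the lists within a comparison. The 31 lists gave 145 tests. They hold p53 targets, repair pathways, replication, mitosis, histones, apoptosis, inflammatory secretome, interferon-stimulated genes, stress responses, sterol synthesis, NRF2 targets, lysosome, hypoxia, matrix, neural and glial progenitors, drug transporters, 22 genes of 10q26 around MGMT, ribosomal proteins, mitochondrial transcripts, structural RNAs and markers of other cell types. Lists overlap: TRIM22 is in the p53 and interferon lists, SLC7A11 in the stress and NRF2 lists, and ABCC3 in the NRF2 and drug transporter lists. PCNA, FEN1, MKI67, BNIP3, SESN2, VEGFA and BAX are also in more than 1 list. Camera with an estimated correlation and fry were run beside it. Groups, comparisons, tests, lists and alternatives were chosen before the data were examined, except where the closing section says otherwise.

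Genes were named by a fixed rule: the 10 largest rises and falls of the averaged TMZ effect and of KO2 against KO1, the 5 largest in the other comparisons, and, for each list called, the 4 members with the smallest p-values in the list's direction and 2 in the other direction. A rise or fall had to pass the threshold, reach 5 CPM in a group compared and, outside the difference, separate every library of the groups compared. Names without an approved symbol, antisense and pseudogene names were passed over for these. MGMT, CDKN1A, MDM2, MKI67 and the tested genes of 10q26 were added whatever their result. The text gives examples from these. Some genes that the rule names are not reported here. Where a group held 0 counts, a fold is a lower bound against 3 counts over the group, with the counts of the other group taken as observed.

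The fit was tested on simulated counts with the same libraries and 200 changed genes among 15850. Changes of 2-fold were recovered in 95.5% of cases for the averaged effect, 80.6% in KO1, 85.1% in KO2, 73.1% for the difference and 83.6% between the lines. Changes of 1.5-fold in the difference were recovered in 20.9% of cases. False calls made up 2.67%, 3.11%, 2.98%, 7.81% and 1.92% of the calls in these 5 comparisons. Of 28 lists tested, only the list seeded with changes of 2-fold was called. Genes were drawn independently, so this cannot show false list calls that arise from correlation between genes. The changed genes averaged at least 1 CPM and were far fewer than those called in the data. Apart from the changed genes, every library had the same mean levels, and each gene had the same dispersion in all groups. The wider spread between the KO2 control replicates was therefore not simulated, and the false-call shares do not cover it.

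Alternatives were scaling by DESeq2 size factors, total count or upper quartile, or with the 10 most abundant genes left out, and no filter or a floor of 1 CPM in 4 libraries. Others were DESeq2 1.42.0, limma-voom, a change of at least 2-fold, an adjusted p under 0.01, the replicate number as a block, an additive model, only the 4 libraries compared, and leaving out each library in turn. A count of calls was taken as the same within 1.5 times.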

Results

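Total RNA, depleted of ribosomal RNA, was sequenced from KO1 and KO2, a pair of lines derived from U251, an established human glioma cell line. The sample titles name both as MGMT knockouts, whereas the sample descriptions name the knocked-out element as an enhancer of MGMT, so the labels leave open what was deleted. MGMT encodes the enzyme that removes alkyl groups from the guanine bases that temozolomide (TMZ), a DNA-alkylating drug used against glioma, modifies. Each line received DMSO (control) or 1 mM TMZ for 72 h, with 2 libraries in each of the 4 groups. Counts assigned to genes ran from 10937909 to 16542371 per library. Levels are counts scaled to library size (CPM), as the group mean ± SD (n = 2), and log2 fold changes are given ± SE. This SE is derived from the F-test and can be too small where a group held few counts. Nothing in the labels says that the replicates were separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. The first principal component of the log2 CPM values held 45.4% of the variance and the second 33.3%, and in both components each replicate lay nearest its partner. The KO2 control replicates differed most, with a chi-square per degree of freedom of 10.9 against 1.91 to 3.83 in the other groups, and with 2.73% and 1.63% of their reads not aligned. This bears on every comparison that uses KO2 control libraries.

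MGMT was close to the limit of detection in KO1 and was not detected in KO2. The KO1 control libraries held 14 and 3 MGMT counts and the KO1 TMZ libraries 14 and 8, while all 4 KO2 libraries held 0. A count of 0 was taken to allow at most 3 counts over the group, and the KO1 counts were taken as observed. On that basis MGMT was at least 6.93-fold higher in KO1 control than in KO2 control cells. It was at least 8.11-fold higher in KO1 TMZ than in KO2 TMZ cells. The edgeR test between the control groups passed the threshold (adjusted p = 0.0069), and it no longer passed without KO1_control replicate 1, which held most of the KO1 control counts (adjusted p = 0.15). Without that library KO1 control has 3 counts, no more than the floor, and the bound between the control groups is lost. No unedited U251 library is among the samples, so neither the labels of the lines nor the effect of the deletion can be checked against a parent. These floors cover only the counting error of the group with 0 counts, not that of the KO1 counts.

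The first comparison sets TMZ against control cells, averaged over both lines. After TMZ, immediate early, glial and NRF2 target genes were lower, and interferon-stimulated and integrated stress response genes were higher. With an estimated correlation between genes, camera kept the integrated stress response list (adjusted p = 0.037) but not the glial, NRF2 or interferon lists (0.14, 0.11 and 0.14). For the immediate early genes, a brief stimulus of the control cells was not excluded. FOS, a subunit of the AP-1 transcription factor, went from 825 ± 14.3 to 8.43 ± 0.312 CPM in KO1 and from 814 ± 30.7 to 8.53 ± 0.873 CPM in KO2. GFAP, the intermediate filament of astrocytes, went from 6215 ± 37.2 to 562 ± 82.3 CPM in KO1 and from 1796 ± 13.2 to 471 ± 7.08 CPM in KO2. ISG15, a ubiquitin-like protein induced by interferon, rose from 157 ± 2.29 to 2741 ± 69.7 CPM in KO1 and from 61.4 ± 3.18 to 606 ± 108 CPM in KO2. DDIT3, the stress transcription factor CHOP, rose from 9.45 ± 0.425 to 116 ± 9.57 CPM in KO1 and from 6.41 ± 0.42 to 59.9 ± 0.181 CPM in KO2. In the edgeR quasi-likelihood test, 9095 of 15850 genes passed an adjusted p of 0.05, with 4533 higher and 4562 lower after TMZ, and 946 rose and 1057 fell by at least 2-fold. Changes are relative to the tested genes as a whole: scaling by the total count alone moved the median gene by 0.18 on the log2 scale and gave 6387 higher and 3124 lower genes.

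The steepest falls were those of FOSB (-6.84 ± 0.09), FOS (-6.59 ± 0.07), FOXI1 (-4.09 ± 0.35), PSD4 (-3.74 ± 0.07), KRT15 (-3.63 ± 0.07) and EGR1 (-3.47 ± 0.06). FOSB and EGR1, like FOS, are immediate early genes, which growth factor signals switch on within minutes. AKR1B10 (-3.25 ± 0.25) and ALDH3A1 (-3.24 ± 0.15), both enzymes that clear reactive aldehydes, AK5 (-3.24 ± 0.18) and SCUBE3 (-3.16 ± 0.10) completed the 10 largest falls. The 10 largest rises were led by genes of the antiviral response. MX2, a GTPase that blocks viruses, went from 0.95 ± 0.833 to 229 ± 10.2 CPM in KO1 and from 0.434 ± 0.153 to 19.6 ± 4.11 CPM in KO2. RSAD2 (6.38 ± 0.24), OAS2 (5.72 ± 0.17), OAS1 (5.71 ± 0.11), CMPK2 (5.28 ± 0.18), SLC15A3 (5.18 ± 0.19) and OASL (5.00 ± 0.11) rose from low control levels in both lines. HSH2D, XAF1 and BATF2 had at most 2 counts over the KO1 control libraries together, so only their levels are given. After TMZ they stood at 29.7 ± 3.97, 38.8 ± 1.85 and 14.9 ± 0.0115 CPM in KO1 and at 3.21 ± 0.487, 1.39 ± 0.979 and 2.00 ± 0.299 CPM in KO2.

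Of 37 interferon-stimulated genes tested, 37 rose, with a median log2 fold change of 3.03 (camera adjusted p = 3.9e-30, adjusted p = 0.14 with an estimated correlation). MX1 rose by 4.85 ± 0.09 and IFI6, a mitochondrial antiviral protein, by 3.78 ± 0.08. The integrated stress response is a programme that ATF4 drives, for example when amino acids run short or unfolded proteins build up. Of 27 of its genes 22 rose and 2 fell (median 1.07, camera adjusted p = 1.1e-11). Among the lists fixed before the counts were examined, this was the averaged comparison's only call that held with an estimated correlation, at an adjusted p of 0.037. TRIB3, a pseudokinase, rose by 2.94 ± 0.06, and SLC7A5 and SLC3A2, the chains of an amino acid transporter, rose from 77.8 ± 1.67 to 333 ± 5.58 CPM and from 273 ± 5.55 to 918 ± 8.29 CPM in KO1. SLC7A11, the cystine transporter, moved the other way at -0.42 ± 0.06. Among 19 genes of the inflammatory secretome 13 rose and 2 fell (median 0.95, camera adjusted p = 0.00025, adjusted p = 0.17 with an estimated correlation). The cytokines CXCL8 and IL11 rose by 3.83 ± 0.13 and 2.71 ± 0.09, RELB, a subunit of NF-kB, rose by 1.39 ± 0.07, and the chemokine CCL2 fell by 1.52 on the log2 scale.

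NRF2 target genes, which hold antioxidant and NADPH-producing enzymes, fell: 19 of 22 were lower, 1 was higher and the median was -1.24 (camera adjusted p = 3.2e-09, adjusted p = 0.11 with an estimated correlation). TKT, the transketolase of the pentose phosphate pathway, went from 7996 ± 92.6 to 890 ± 57.5 CPM in KO1 and from 4238 ± 293 to 903 ± 51.0 CPM in KO2. NQO1, a quinone reductase, fell by 1.49 on the log2 scale. Of 13 drug transporter and detoxification genes 11 fell and 1 rose (median -0.83, camera adjusted p = 3.6e-05, adjusted p = 0.11 with an estimated correlation). Among them were ABCC3, a drug efflux pump, at -1.60 ± 0.05 and GSTP1, a glutathione transferase, at -0.93 ± 0.06. ABCC3 belongs to both lists. Neural and glial progenitor genes fell as well, 13 of 17 lower and 1 higher (median -0.74, camera adjusted p = 2.1e-05, adjusted p = 0.14 with an estimated correlation). SOX2 and NES, markers of neural stem cells, changed by -1.56 ± 0.05 and -0.86 ± 0.05, and FABP7, a fatty acid binder of radial glia, by -1.83 ± 0.10.

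Homologous recombination genes rose, 17 of 25 higher and 2 lower (median 0.41, camera adjusted p = 0.0014, adjusted p = 0.17 with an estimated correlation). Examples are BRCA2 at 1.62 ± 0.10, BRCA1 at 0.98 ± 0.07 and XRCC2 at 0.92 ± 0.09. In KO2 alone the list did not pass (7 of 25 higher, 3 lower, median 0.17, camera adjusted p = 0.097). Apoptosis regulators included 12 of 25 higher and 2 lower (median 0.21, camera adjusted p = 0.037, adjusted p = 0.17 with an estimated correlation). The members that rose act both ways: PMAIP1, which promotes cell death, rose by 0.86 ± 0.07, and BIRC2, which inhibits it, by 0.85 ± 0.07. BAX, a pore-forming death effector, fell by 0.40 on the log2 scale. That call was lost with a floor of 1 CPM in 4 libraries (adjusted p = 0.066). The apoptosis list did not pass in KO2 alone (9 of 25 higher, 2 lower, camera adjusted p = 0.11). Of 23 replication-dependent histone genes 13 rose and 2 fell (median 0.92, camera adjusted p = 0.027, adjusted p = 0.17 with an estimated correlation), such as HIST1H2AC at 1.82 ± 0.11 and HIST1H2BK at 1.09 ± 0.13. Histone messages are near-identical copies, so single members are uncertain. The list's call was lost with total count scaling (adjusted p = 0.12), without a filter on low counts (0.064) and with a floor of 1 CPM in 4 libraries (0.068). In KO1 alone the histone list did not pass (8 of 23 higher, 1 lower, camera adjusted p = 0.081). CDKN1A, a cell cycle inhibitor, and MDM2, a ubiquitin ligase, rose by 0.77 ± 0.05 and 0.32 ± 0.07, but the 37 p53 targets as a list did not pass (16 higher, 9 lower, camera adjusted p = 0.059).

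Cytosolic ribosomal protein genes fell by a little, 58 of 75 lower and 0 higher (median -0.24, camera adjusted p = 1.6e-07, adjusted p = 0.53 with an estimated correlation). RPL3, for example, changed by -0.86 ± 0.05. Scaled by the total count alone, 24 were lower and 8 higher. Many of these genes have processed pseudogenes, so their single values are uncertain. Transcripts of the mitochondrial genome fell in 14 of 15 cases and rose in 0 (median -0.77, camera adjusted p = 3.3e-08, adjusted p = 0.22 with an estimated correlation). Their share of the gene counts went from 6.67% and 6.59% to 4.13% and 4.09% in KO1 and from 5.07% and 4.59% to 3.71% and 3.71% in KO2. Adjusted over the list alone, the counts of the 11 called lists were the same as over all genes tested, except for homologous recombination (18 higher, 2 lower) and ribosomal proteins (1 higher, 59 lower). Of the other repair lists, mismatch repair had 6 of 14 higher and 5 lower (camera adjusted p = 0.37), and total count scaling gave it 8 higher and 1 lower. Camera also gave no call for base excision repair, 4 of 19 higher and 10 lower (adjusted p = 0.10), direct reversal, 1 of 3 higher (0.59), the Fanconi anaemia pathway, 5 of 15 higher and 3 lower (0.59) and end joining, 4 of 11 higher and 2 lower (0.56). DNA replication had 23 of 45 higher and 10 lower (camera adjusted p = 0.060) and mitosis 13 of 47 higher and 18 lower (0.46). Scaled by the total count alone, the mitosis split turned to 24 higher and 10 lower. MKI67, a marker of cycling cells and the nearest listed neighbour of MGMT, rose by 0.17 ± 0.05, which did not hold without KO1_control replicate 1 (edgeR adjusted p = 0.071). The unfolded protein response (10 of 17 higher, 3 lower, camera adjusted p = 0.080), cholesterol synthesis (4 of 24 higher, 12 lower, 0.080), lysosome and autophagy (8 of 27 higher, 10 lower, 0.59), hypoxia and glycolysis (12 of 25 higher, 7 lower, 0.59) and the 10q26 genes around MGMT (4 of 15 higher, 5 lower, 0.44) did not pass. Total count scaling turned the lysosome split to 13 higher and 7 lower and the matrix split that follows to 13 higher and 11 lower. It gave cholesterol synthesis 8 higher and 11 lower, with a median of 0.03 against -0.15. Extracellular matrix genes did not pass either (13 of 29 higher, 14 lower, camera adjusted p = 0.37), with a median of 0.03 against a mean of -0.09 and a test direction down. Markers of epithelial cells (1 of 6 higher, 1 lower, camera adjusted p = 0.73), endothelial cells (0 of 6 higher, 3 lower, 0.16) and neurons (2 of 7 higher, 2 lower, 0.92) and 3 structural noncoding RNAs (1 higher, 2 lower, 0.10) did not pass, and leukocyte markers (2 tested) and liver and erythroid markers (1 tested) were too few to test.

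**Figure D1:**
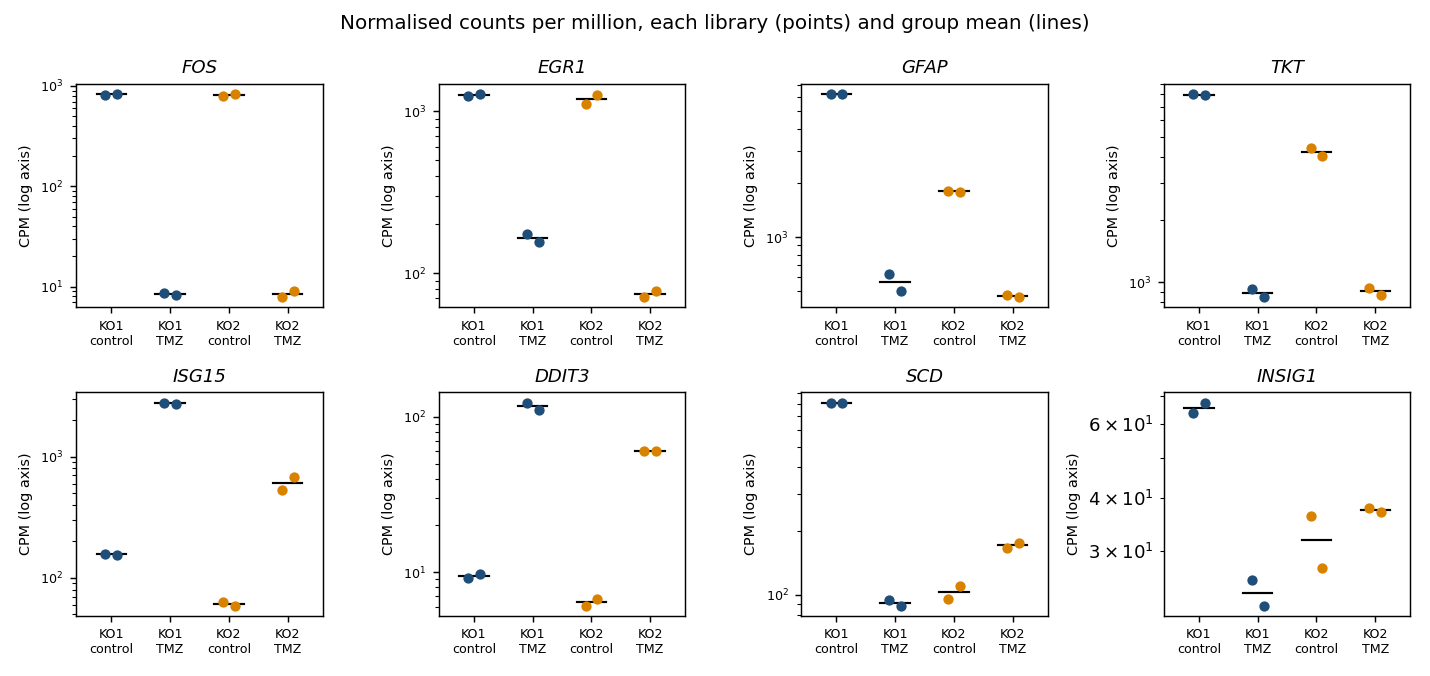
Normalised CPM on a log axis for FOS, EGR1, GFAP, TKT, ISG15, DDIT3, SCD and INSIG1, with a point for each of the 8 libraries and a line at each group mean. FOS fell to near 8.5 CPM in both lines, ISG15 and DDIT3 rose in both, and SCD fell in KO1 and rose in KO2.

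Within KO1, more genes passed than within KO2, and replication genes were higher after TMZ while mitotic and sterol genes were lower. None of these 3 lists kept its camera call with an estimated correlation (adjusted p = 0.10, 0.26 and 0.10), and the mitosis call also depended on the scaling. DTL, a factor of the replication-coupled ubiquitin ligase, rose from 41.4 ± 2.53 to 133 ± 1.55 CPM. KIF20A, a kinesin of cell division, fell from 128 ± 6.44 to 51.0 ± 6.79 CPM. INSIG1, a sterol sensor, fell from 65.7 ± 2.72 to 23.9 ± 2.32 CPM. The edgeR test called 7968 genes, 3958 higher and 4010 lower, of which 1104 and 1328 changed by at least 2-fold. With total count scaling the split was 5340 higher and 2994 lower. The largest falls were those of FOSB (-7.05 ± 0.13), FOS (-6.61 ± 0.10), FOXI1 (-5.57 ± 0.59), AKR1B10 (-5.25 ± 0.32) and CDH5, the cadherin of endothelial cells (-4.82 ± 0.22). The largest rises were those of HSH2D, XAF1, RSAD2 (8.25 ± 0.27), BATF2 and MX2 (7.90 ± 0.23). FOXI1 had 1 and 2 counts in the KO1 TMZ libraries. RSAD2 had 2 and 6 and MX2 17 and 4 counts in the KO1 control libraries. The standard errors given for FOXI1, RSAD2 and MX2 are therefore too small.

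Of 45 DNA replication genes 29 rose and 2 fell in KO1 (median 0.41, camera adjusted p = 6.1e-06, adjusted p = 0.10 with an estimated correlation). ORC6, CDC6 and CDT1, which license replication origins, rose by 1.29 ± 0.09, 1.10 ± 0.08 and 0.96 ± 0.09, and TYMS, which makes thymidylate, changed by -0.49 ± 0.09. Homologous recombination had 18 of 25 higher and 1 lower (median 0.52, camera adjusted p = 0.00010, adjusted p = 0.11 with an estimated correlation). BRIP1, a helicase that binds BRCA1, rose from 21.9 ± 0.0755 to 50.3 ± 2.55 CPM. Mitosis genes went the other way, 21 of 47 lower and 8 higher (median -0.19, camera adjusted p = 0.025, adjusted p = 0.26 with an estimated correlation). The mitosis call was lost with total count scaling (adjusted p = 0.22), where 13 were higher and 11 lower. CCNB1 (cyclin B), PLK1 and CDC20 changed by -0.88 ± 0.07, -1.19 ± 0.11 and -0.91 ± 0.09. Cholesterol synthesis genes fell in 12 of 24 cases and rose in 0 (median -0.34, camera adjusted p = 0.00081, adjusted p = 0.10 with an estimated correlation). Examples are INSIG1 at -1.45 ± 0.13 and SREBF2, the transcription factor of the pathway, at -0.70 ± 0.08. All 37 interferon-stimulated genes rose (median 3.47, camera adjusted p = 1.5e-32, adjusted p = 0.10 with an estimated correlation). The integrated stress response had 22 of 27 higher and 2 lower (median 1.19, camera adjusted p = 1.4e-11, adjusted p = 0.039 with an estimated correlation). The inflammatory secretome had 10 of 19 higher and 3 lower (median 1.03, camera adjusted p = 0.0057, adjusted p = 0.21 with an estimated correlation). Apoptosis regulators had 13 of 25 higher and 3 lower (median 0.42, camera adjusted p = 0.017, adjusted p = 0.13 with an estimated correlation).

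NRF2 targets fell in 20 of 22 cases in KO1 (median -1.66, camera adjusted p = 2.9e-12, adjusted p = 0.063 with an estimated correlation). FTL, the light chain of the iron store ferritin, went from 12157 ± 338 to 3031 ± 219 CPM. Drug transporters and detoxification had 11 of 13 lower and 1 higher (median -1.40, camera adjusted p = 4.5e-06, adjusted p = 0.063 with an estimated correlation). Neural and glial progenitor genes had 12 of 17 lower and 1 higher (median -0.87, camera adjusted p = 1.6e-05, adjusted p = 0.10 with an estimated correlation). Ribosomal proteins had 59 of 75 lower and 0 higher (median -0.40, camera adjusted p = 3.2e-11, adjusted p = 0.35 with an estimated correlation). Mitochondrial transcripts had 14 of 15 lower (median -0.84, camera adjusted p = 7.2e-09, adjusted p = 0.20 with an estimated correlation). Adjusted over the list alone, counts of the called lists differed from those over all genes tested for mitosis (9 higher, 21 lower), the integrated stress response (23 higher, 2 lower) and neural and glial genes (2 higher, 12 lower).

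Within KO2, interferon-stimulated and integrated stress response genes were again higher after TMZ, and base excision repair genes were lower. With an estimated correlation, camera kept the stress list (adjusted p = 0.028) but not the interferon or base excision repair lists (0.14 and 0.24), and the latter call also fell to other settings given with it. GDF15, a stress-induced cytokine and p53 target, rose from 83.3 ± 14.6 to 524 ± 31.3 CPM, and GADD45A, a p53 target induced by DNA damage, from 54.2 ± 4.34 to 147 ± 3.47 CPM. NTHL1, a glycosylase that excises oxidised pyrimidines, fell from 17.9 ± 3.69 to 6.79 ± 0.495 CPM. The edgeR test called 6560 genes, 3236 higher and 3324 lower, with 794 and 794 changed by at least 2-fold. With total count scaling the split was 5254 higher and 2091 lower. The largest rises were MX2 (5.44 ± 0.32), OAS1 (5.06 ± 0.16), OAS2 (4.91 ± 0.27), MX1 (4.72 ± 0.14) and RSAD2 (4.51 ± 0.40), and the largest falls were FOSB (-6.63 ± 0.12), FOS (-6.57 ± 0.10), EGR1 (1190 ± 108 to 74.3 ± 4.03 CPM), ZNF385B (-3.42 ± 0.28) and PSD4 (-3.36 ± 0.10). RSAD2 had 0 and 8 counts and MX2 had 4 and 8 in the KO2 control libraries, so their values and ranks are uncertain.

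Among 37 p53 targets 15 rose and 7 fell in KO2 (median 0.20, camera adjusted p = 0.027, adjusted p = 0.24 with an estimated correlation). SESN2, a stress-induced regulator of metabolism, rose by 1.51 ± 0.11, while PLK2 and BTG2 changed by -0.79 ± 0.07 and -1.26 ± 0.13. The list shares TRIM22, an antiviral protein, with the interferon list. In KO1 the p53 list had 15 higher and 11 lower (camera adjusted p = 0.059), and its difference between the lines did not pass (0.19). Base excision repair had 11 of 19 lower and 2 higher (median -0.37, camera adjusted p = 0.041, adjusted p = 0.24 with an estimated correlation). Examples are the glycosylases NEIL1 and UNG at -1.03 ± 0.13 and -0.66 ± 0.09, and TDG, the thymine DNA glycosylase, at 0.70 ± 0.10. That call was lost with total count scaling (adjusted p = 0.074), a floor of 1 CPM in 4 libraries (0.070) and without KO2_control replicate 1 (0.055). Base excision repair in KO1 had 9 lower and 5 higher (median -0.25, camera adjusted p = 0.24), and its difference between the lines did not pass (0.35). Histones had 14 of 23 higher and 3 lower (median 1.27, camera adjusted p = 0.017, adjusted p = 0.15 with an estimated correlation). The histone call was lost with total count scaling (adjusted p = 0.11), a floor of 1 CPM in 4 libraries (0.13) and without KO2_control replicate 2 (0.068). The inflammatory secretome had 15 of 19 higher and 1 lower (median 1.06, camera adjusted p = 4.1e-06, adjusted p = 0.14 with an estimated correlation). An example is TNFAIP3, an inhibitor of NF-kB, at 1.98 ± 0.18. All 37 interferon-stimulated genes rose (median 2.79, camera adjusted p = 6.8e-35, adjusted p = 0.14 with an estimated correlation). The integrated stress response had 20 of 27 higher and 1 lower (median 1.11, camera adjusted p = 1.3e-13, adjusted p = 0.028 with an estimated correlation). An example is CHAC1, which breaks down glutathione, at 2.11 ± 0.12. NRF2 targets had 14 of 22 lower and 2 higher (median -0.81, camera adjusted p = 9.1e-06, adjusted p = 0.14 with an estimated correlation). Neural and glial genes had 10 of 17 lower and 2 higher (median -0.58, camera adjusted p = 6.0e-05, adjusted p = 0.14 with an estimated correlation). Drug transporters and detoxification had 6 of 13 lower (median -0.50, camera adjusted p = 0.0066, adjusted p = 0.14 with an estimated correlation). Mitochondrial transcripts had 12 of 15 lower (median -0.70, camera adjusted p = 8.2e-07, adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, counts of the called lists differed for NRF2 targets (2 higher, 15 lower) and neural and glial genes (2 higher, 11 lower). Ribosomal proteins did not pass in KO2 (3 of 75 higher, 18 lower, camera adjusted p = 0.077), and total count scaling turned that split to 20 higher and 3 lower.

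**Figure D2:**
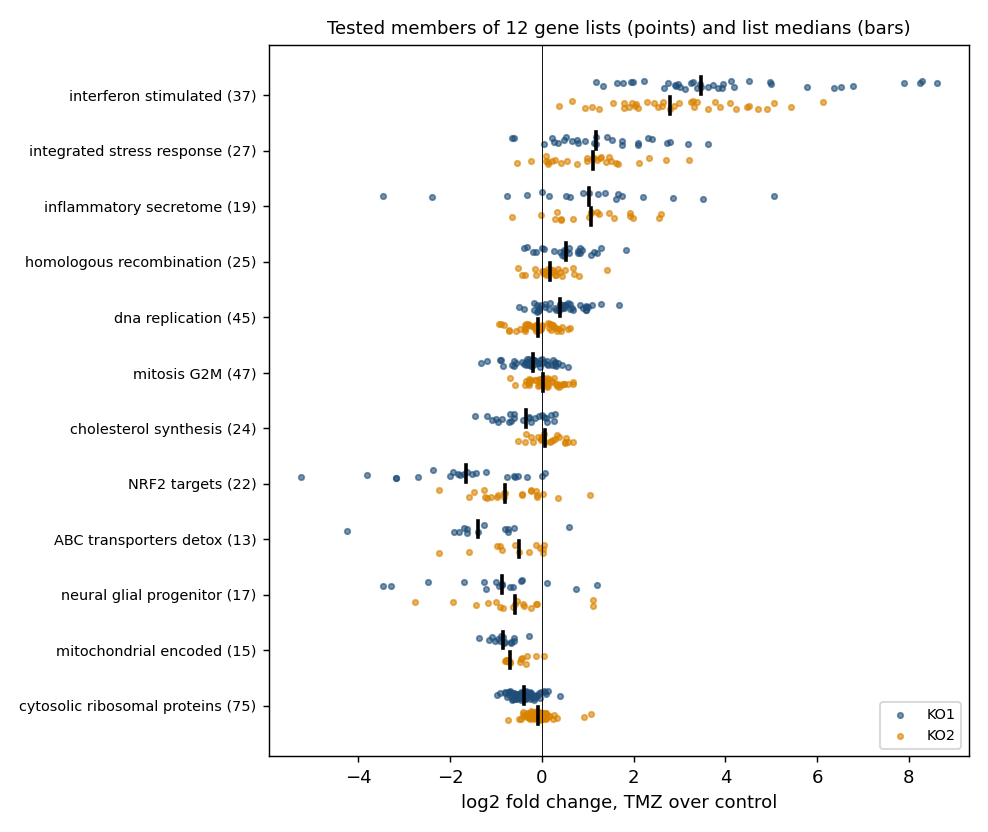
Log2 fold change of TMZ over control for the tested members of 12 gene lists in KO1 and KO2, with a point per gene and a bar at each list's median. All 37 interferon-stimulated genes lie above 0 in both lines, and the medians of the NRF2 targets lie below 0 in both (-1.66 and -0.81).

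The lines were then set side by side. Across the 15850 tested genes the KO1 and KO2 log2 fold changes had a Pearson r of 0.633 and a Spearman rho of 0.649, where genes are not independent replicates and the lines share no libraries. With no filter on low counts the Pearson r was 0.203. Genes called in both lines numbered 4881, and 4714 of them (96.6%) moved the same way, 2320 up and 2394 down against 808 and 841 for independent lists. All 167 called in opposite directions also passed the test of the difference, which largely follows from their selection, since opposite effects add up in a difference. The changes were larger in KO1, with a median absolute log2 fold change of 0.475 against 0.372 in KO2.

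**Figure D3:**
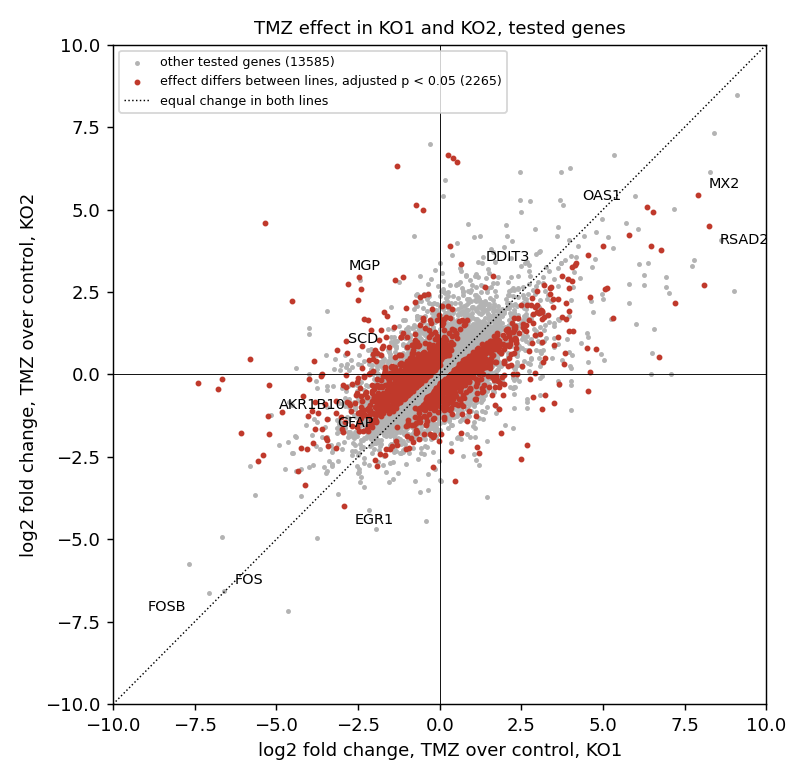
Log2 fold change of TMZ over control in KO1 (x axis) and KO2 (y axis), with a point for each of the 15850 tested genes, the 2265 genes whose effect differed between the lines in red and a dotted line at equal change. Genes such as FOS and FOSB lie near the dotted line, whereas SCD and MGP fell in KO1 and rose in KO2.

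The difference of the TMZ effect between the lines was tested as an interaction, KO2 minus KO1. It uses the same control libraries as the comparison of control cells, with the opposite sign, so these results are not independent. A difference can arise from unequal control levels as well as from unequal levels after TMZ. SCD, the desaturase that makes monounsaturated fatty acids, fell from 808 ± 1.71 to 91.5 ± 4.03 CPM in KO1 and rose from 103 ± 10.4 to 171 ± 6.84 CPM in KO2, a difference of 3.87 ± 0.11. MGP, an inhibitor of calcification, fell from 12.5 ± 0.929 to 5.75 ± 0.433 CPM in KO1 and rose from 0.549 ± 0.0853 to 4.32 ± 0.649 CPM in KO2. MCM2, a subunit of the replicative helicase, rose from 170 ± 1.57 to 223 ± 5.03 CPM in KO1 and fell from 287 ± 0.697 to 222 ± 0.00099 CPM in KO2. The edgeR interaction test called 2265 genes, 1099 with a higher and 1166 with a lower log2 change in KO2, and upper-quartile scaling gave 1346 and 872. By the fitted values, whether or not the change in either line passed, 1158 of these had log2 fold changes of the same sign and larger in size in KO1, 232 of the same sign and larger in size in KO2, and 875 of opposite sign. The number rested on single libraries: it was 1192, 1254, 1324 and 1238 without KO1_control replicate 1, KO1_control replicate 2, KO1_TMZ replicate 1 and KO1_TMZ replicate 2. It was 3495 and 3644 without KO2_control replicates 1 and 2, and 1405 and 1505 without KO2_TMZ replicates 1 and 2. The largest positive differences after MGP (4.06 ± 0.40) were those of AKR1B10, SCD, CDH5 (3.67 ± 0.29) and the amino acid transporter SLC38A3 (3.51 ± 0.28). The largest negative ones rested on 1 or 2 counts over the KO1 control libraries, so levels are given. In KO1, BATF2 and UNC5B reached 14.9 ± 0.0115 and 1.35 ± 0.774 CPM after TMZ. In KO2, BATF2 went from 0.291 ± 0.0666 to 2.00 ± 0.299 CPM and UNC5B from 17.9 ± 1.01 to 12.7 ± 0.14 CPM.

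DNA replication genes had the smallest camera p of the list differences at the preset correlation, with 29 of 45 lower and 0 higher in KO2 (median -0.57, camera adjusted p = 1.0e-16, adjusted p = 0.033 with an estimated correlation), such as DTL at -1.31 ± 0.13. FEN1, which trims Okazaki fragments, differed by -0.90 ± 0.11 and MCM3 by -0.71 ± 0.09. Cholesterol synthesis (9 of 24 higher, 0 lower, median 0.42, camera adjusted p = 3.8e-10), NRF2 targets (15 of 22 higher, 0 lower, median 0.65, camera adjusted p = 8.7e-15) and drug transporters and detoxification (8 of 13 higher, 0 lower, median 0.68, camera adjusted p = 5.4e-06) also differed, with adjusted p = 0.033, 0.045 and 0.0498 with an estimated correlation. INSIG1 differed by 1.69 ± 0.18, DHCR7, a late enzyme of sterol synthesis, by 0.88 ± 0.11, and FTL by 1.56 ± 0.12. HMOX1, which degrades haem, fell from 83.5 ± 6.27 to 48.8 ± 8.56 CPM in KO1 and rose from 37.2 ± 6.52 to 77.1 ± 2.19 CPM in KO2. Interferon-stimulated genes rose less in KO2, with 26 of 37 lower and 0 higher (median -0.91, camera adjusted p = 4.0e-16, adjusted p = 0.18 with an estimated correlation), including USP18, which restrains interferon signalling, at -1.42 ± 0.16 and IFI35 at -1.23 ± 0.14. Mitosis genes were higher in 16 of 47 cases and lower in 1 (median 0.29, camera adjusted p = 2.0e-06, adjusted p = 0.12 with an estimated correlation). Examples are KIF20A at 1.29 ± 0.13 and the kinase AURKA at 0.65 ± 0.10. Homologous recombination (0 of 25 higher, 6 lower, median -0.35, camera adjusted p = 0.00015), mismatch repair (0 of 14 higher, 5 lower, median -0.28, 0.0044) and the Fanconi anaemia pathway (0 of 15 higher, 1 lower, median -0.29, 0.018) were lower, with adjusted p = 0.12, 0.12 and 0.15 with an estimated correlation. BARD1, the partner of BRCA1, differed by -0.79 ± 0.14, PCNA, the replication clamp, by -0.78 ± 0.11 and FAAP100 by -0.55 ± 0.11.

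The integrated stress response differed in 10 of 27 cases downward and 3 upward (median -0.29, camera adjusted p = 0.0014, adjusted p = 0.10 with an estimated correlation). Examples are PPP1R15A, the phosphatase subunit that ends the response, at -1.06 ± 0.10 and VEGFA, the vascular growth factor, at 0.64 ± 0.12. Neural and glial genes had 5 of 17 higher and 1 lower (median 0.32, camera adjusted p = 0.0029, adjusted p = 0.18 with an estimated correlation), GFAP at 1.53 ± 0.11 and NOTCH1, a receptor of progenitor cells, at -1.12 ± 0.13. Ribosomal proteins had 28 of 75 higher and 0 lower (median 0.32, camera adjusted p = 1.5e-13, adjusted p = 0.35 with an estimated correlation). Mitochondrial transcripts had 5 of 15 higher and 0 lower (median 0.19, camera adjusted p = 0.00016, adjusted p = 0.30 with an estimated correlation). Lysosome and autophagy genes had 4 of 27 higher (median 0.15, camera adjusted p = 0.046, adjusted p = 0.30 with an estimated correlation). An example is CTSB, a lysosomal protease, at 0.65 ± 0.09. That call was lost without KO1_control replicate 1 (adjusted p = 0.068), KO1_TMZ replicate 1 (0.082), KO1_TMZ replicate 2 (0.057), KO2_control replicate 2 (0.093) and KO2_TMZ replicate 1 (0.064). Endothelial markers had 2 of 6 higher (median 0.59, camera adjusted p = 0.039, adjusted p = 0.18 with an estimated correlation), CDH5 and KDR, a receptor for VEGF (1.22 ± 0.15). The endothelial call was lost without KO1_control replicate 2 (adjusted p = 0.098) and KO2_TMZ replicate 1 (0.064). Adjusted over the list alone, the counts were 32 lower for DNA replication, 14 higher for cholesterol synthesis, 16 higher for NRF2 targets, 9 higher and 1 lower for drug transporters, 27 lower and 1 higher for interferon-stimulated genes, 23 higher and 2 lower for mitosis, 7 lower for mismatch repair, 11 lower and 3 higher for the integrated stress response, 8 higher and 1 lower for neural and glial genes and 37 higher for ribosomal proteins, and the same as over all genes tested for the other 5 called lists.

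The last comparison set the control cells of the lines against each other, KO2 over KO1. It is not independent of the difference of the TMZ effect, which uses the same control libraries with the opposite sign. KO2 held more replication and mitosis transcripts and fewer interferon-stimulated, matrix, NRF2 and glial transcripts. None of the 11 calls in this comparison on the lists fixed before the counts were examined held with an estimated correlation, where the lowest camera adjusted p was 0.14. TGFBI, a matrix protein induced by TGF-beta, stood at 390 ± 4.96 CPM in KO1 and 48.1 ± 1.09 CPM in KO2. KRT18, a keratin of simple epithelia, stood at 17.6 ± 0.49 CPM in KO1 and 66.5 ± 5.37 CPM in KO2. The edgeR test called 5402 genes, 2721 higher and 2681 lower in KO2, with 748 and 727 changed by at least 2-fold. Since both are edited lines, this difference cannot be assigned to either deletion. CHST15, CUX2, PAX7 and USP43 had 0 counts in KO1 control cells and were at least 198-fold, 69.0-fold, 59.4-fold and 39.5-fold higher in KO2 against a floor of 3 counts over the group. PAX7 and CUX2 are transcription factors of muscle precursors and of cortical neurons. TNFSF18, TRIM29, KCND3, UNC5B, ARRB1 and RFLNA completed the 10 largest rises, at 75.3 ± 2.22, 25.6 ± 1.16, 33.8 ± 5.06, 17.9 ± 1.01, 11.5 ± 0.451 and 34.6 ± 2.47 CPM in KO2 against 0.0906 ± 0.128, 0.0453 ± 0.064, 0.0903 ± 0.128, 0.0451 ± 0.0638, 0.0453 ± 0.064 and 0.181 ± 0.000432 CPM in KO1. Among the largest falls, IGSF1 changed by -5.89 ± 0.21, PLXNA4, a receptor for semaphorins, by -5.15 ± 0.30 and SLC38A3 by -5.05 ± 0.15, and the transcription factor MAF stood at 12.1 ± 0.604 CPM in KO1 and 0.0746 ± 0.00971 CPM in KO2.

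Of the 15 tested genes listed around MGMT on 10q26, 8 were higher and 3 lower in KO2 (camera adjusted p = 0.10, adjusted p = 0.27 with an estimated correlation, and 9 higher and 3 lower adjusted over the list alone), with a median of 0.34 and a mean of -0.11, the latter pulled down by MGMT itself. The test direction was up. MKI67, the listed gene next to MGMT, stood at 491 ± 11.8 CPM in KO1 and 698 ± 57.5 CPM in KO2 (0.51 ± 0.07), and PTPRE, a phosphatase beyond it, at 0.0453 ± 0.064 and 1.35 ± 0.765 CPM. ADAM12, a metalloprotease, was lower in KO2 (-1.07 ± 0.10), as was C10orf90 at 1.36 ± 0.00324 against 0.183 ± 0.0284 CPM, an edgeR call that did not hold without KO1_control replicate 1, KO1_control replicate 2 or KO2_control replicate 1 (adjusted p = 0.071, 0.071 and 0.052). DOCK1 (0.45 ± 0.09), BNIP3 (0.34 ± 0.07), DPYSL4 (0.63 ± 0.10), STK32C (0.75 ± 0.18), PWWP2B (0.77 ± 0.17) and INPP5A (0.43 ± 0.11) were higher. GLRX3 (0.22 ± 0.09), PPP2R2D (0.04 ± 0.09), JAKMIP3 (-0.09 ± 0.20) and LRRC27 (-0.04 ± 0.16) did not pass.

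**Figure D4:**
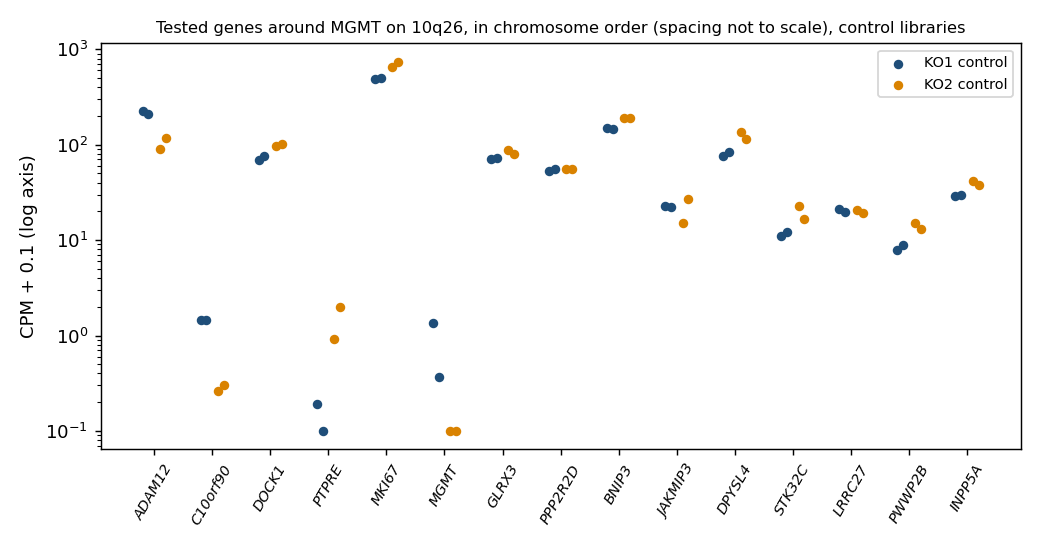
CPM plus 0.1 on a log axis for the 15 tested genes around MGMT in chromosome order, with a point for each control library of KO1 and KO2. MGMT has 0 counts in both KO2 control libraries, and MKI67 is the most abundant of the genes.

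DNA replication genes were higher in KO2 control cells in 31 of 45 cases and lower in 0 (median 0.38, camera adjusted p = 2.1e-11, adjusted p = 0.14 with an estimated correlation). Examples are ORC6 at 1.07 ± 0.09 and MCM2 at 0.75 ± 0.07. Mitosis genes were higher in 24 of 47 cases and lower in 0 (median 0.23, camera adjusted p = 2.0e-07, adjusted p = 0.15 with an estimated correlation). An example is PRC1, which bundles spindle microtubules, at 0.83 ± 0.07. Interferon-stimulated genes were lower in 25 of 37 cases and higher in 1 (median -1.02, camera adjusted p = 2.3e-13, adjusted p = 0.25 with an estimated correlation). Examples are PARP9 and DTX3L, which act as a pair in DNA damage and interferon signalling, at -1.62 ± 0.10 and -1.55 ± 0.10. Matrix genes were lower in 17 of 29 cases and higher in 2 (median -0.44, camera adjusted p = 3.9e-05, adjusted p = 0.23 with an estimated correlation). Examples are FN1, fibronectin, at -1.44 ± 0.09 and ANKRD1, a target of the YAP pathway, at 2.35 ± 0.09. NRF2 targets were lower in 16 of 22 cases (median -0.72, camera adjusted p = 2.5e-08, adjusted p = 0.15 with an estimated correlation). Examples are AKR1C3 at -2.66 ± 0.13 and AKR1C1 at -3.01 ± 0.19, near-identical aldo-keto reductases whose split is uncertain. Cholesterol synthesis (9 of 24 lower, 1 higher, median -0.30, camera adjusted p = 0.0021), lysosome and autophagy (16 of 27 lower, 2 higher, median -0.30, 0.0021) and neural and glial genes (9 of 17 lower, 3 higher, median -0.36, 0.0046) were lower, with adjusted p = 0.15, 0.25 and 0.25 with an estimated correlation. SREBF2 differed by -0.72 ± 0.08, CTSL, a lysosomal protease, by -1.03 ± 0.08 and FABP7 by -3.14 ± 0.13. Ribosomal proteins were higher in 38 of 75 cases and lower in 3 (median 0.26, camera adjusted p = 4.1e-07, adjusted p = 0.55 with an estimated correlation). Mitochondrial transcripts were lower in 13 of 15 cases (median -0.47, camera adjusted p = 4.1e-07, adjusted p = 0.27 with an estimated correlation). Epithelial markers were higher in 3 of 6 cases (median 1.31, camera adjusted p = 0.010, adjusted p = 0.23 with an estimated correlation), KRT18, KRT8 (2.56 ± 0.19) and the tight junction protein CLDN4 (1.23 ± 0.16). Adjusted over the list alone, the counts were 33 higher for DNA replication, 26 lower and 1 higher for interferon-stimulated genes, 19 lower and 3 higher for matrix genes, 10 lower and 3 higher for neural and glial genes, 40 higher and 5 lower for ribosomal proteins and 14 lower for mitochondrial transcripts, and unchanged for the other 5 called lists.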

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

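The patterns weighed below and the lists used on them were chosen after the main results were seen. What the tests of interferon genes, of ERK feedback genes, of short-lived RNAs and of gene length should show was written before their values were seen. For scaling and leukocyte RNA it was written after, and the single interferon genes to print were also chosen after. A difference between the lines in the TMZ effect, tested as an interaction in edgeR with an adjusted p under 0.05, brought 80 of the genes in the report here. Values are the log2 effect in KO2 minus that in KO1. The genes are grouped by the sign and size of the fitted log2 changes, whether or not the change in either line passed. In 59 genes the fitted changes had the same sign and were larger in size in KO1. Some of these had almost no change in KO2, such as BRIP1 (0.01), SREBF2 (-0.01) and KIF20A (-0.02). The 59 were BATF2 (-5.38), AKR1B10 (3.996), RSAD2 (-3.74), CDH5 (3.67), SLC38A3 (3.51), CMPK2 (-3.01), AKR1C1 (2.99), FOXI1 (2.96), SLC15A3 (-2.58), CXCL8 (-2.46), MX2 (-2.46), ALDH3A1 (1.998), SCUBE3 (1.78), CCL2 (1.75), OAS2 (-1.61), AKR1C3 (1.60), OASL (-1.56), FTL (1.56), GFAP (1.53), TRIM22 (-1.51), USP18 (-1.42), KRT15 (1.41), FABP7 (1.33), DTL (-1.31) and OAS1 (-1.30). They also included KIF20A (1.29), IFI35 (-1.23), BRIP1 (-1.19), PPP1R15A (-1.06), ADAM12 (1.05), TKT (0.94), HIST1H2AC (-0.92), DHCR7 (0.88), GADD45A (-0.85), ISG15 (-0.82), SLC7A5 (-0.81), IFI6 (-0.80), BARD1 (-0.79), CDC6 (-0.78), PSD4 (0.76), CDC20 (0.76), CCNB1 (0.75), GDF15 (-0.74), RELB (-0.72), SREBF2 (0.69), PMAIP1 (-0.69), ORC6 (-0.68), GSTP1 (0.68), CHAC1 (-0.68), CTSB (0.65), NQO1 (0.60), BRCA1 (-0.60), CTSL (0.4998), ATF4 (-0.50), PLK1 (0.49), SLC3A2 (-0.49), BNIP3 (-0.49), TRIB3 (-0.48) and SLC7A11 (0.39). In 4 genes they had the same sign and were larger in size in KO2: EGR1 (-1.07), VEGFA (0.64), FAAP100 (-0.55) and PLK2 (-0.49). In 17 genes the fitted changes had opposite signs: UNC5B (-5.05), TNFSF18 (-4.35), MGP (4.06), SCD (3.87), MAF (2.78), HMOX1 (1.83), INSIG1 (1.69), TGFBI (1.39), KDR (1.22), NOTCH1 (-1.12), CDT1 (-0.97), FEN1 (-0.90), PCNA (-0.78), MCM2 (-0.75), MCM3 (-0.71), AURKA (0.65) and KRT18 (-0.51). BATF2, UNC5B, TNFSF18 and MAF had 1 or 2 counts in a control group, so their fitted values depend on the prior count.

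Of these 80 calls, 62 held with each library left out in turn and 18 were lost without at least 1 library. The number of libraries whose removal alone ended the call was 6 for KRT18, MAF and SLC7A11, 5 for CHAC1 and MX2, 4 for FOXI1, OAS2 and PLK1, 3 for TRIB3 and 2 for CTSL, HIST1H2AC and RSAD2. It was 1 for BNIP3, BRCA1, CMPK2, OAS1, SLC15A3 and SLC3A2. Without KO2_control replicate 2 the RSAD2 difference changed sign, from -3.74 to 1.34 (adjusted p = 0.65), where the KO2 control libraries had 0 and 8 counts. The same library ended the calls of CMPK2 (-1.71), OAS1 (-0.95), OAS2 (-0.63), MX2 (-1.99) and SLC15A3 (-2.12). DESeq2 lost MAF and OAS2, limma-voom lost FOXI1, MAF, OAS2 and RSAD2, and upper-quartile scaling lost KRT18.

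By the same test on lists, 15 differed between the lines. The median differences were -0.57 for DNA replication, -0.28 for mismatch repair, -0.35 for homologous recombination, -0.29 for the Fanconi anaemia pathway, 0.29 for mitosis, -0.91 for interferon-stimulated genes and -0.29 for the integrated stress response. They were 0.42 for cholesterol synthesis, 0.65 for NRF2 targets, 0.15 for lysosome and autophagy, 0.32 for neural and glial genes, 0.68 for drug transporters, 0.32 for ribosomal proteins, 0.19 for mitochondrial transcripts and 0.59 for endothelial markers. With an estimated correlation, the calls for replication, cholesterol synthesis, NRF2 targets and drug transporters held. In KO2 over KO1 control cells, which share libraries with the difference, these lists had medians of the opposite sign (0.38, -0.30, -0.72 and -0.58). The drug transporter list did not pass there (camera adjusted p = 0.30). The mitosis, interferon-stimulated, integrated stress response, ribosomal protein and endothelial lists had medians of the same sign in both comparisons. The lysosome and endothelial calls depended on single libraries, as the report gives.

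A signal outside the gene counts was also higher after TMZ in every library of each line. Reads aligned to more than 1 place made up 18.4% in KO1 TMZ against 16.5% in KO1 control libraries, and 16.9% in KO2 TMZ against 16.4% in KO2 control libraries. Reads in no annotated gene made up 4.86% in KO1 TMZ against 4.57%, and 5.31% in KO2 TMZ against 4.79%. In KO2 these shares nearly met, at 4.46% and 5.13% in the control against 5.14% and 5.49% in the TMZ libraries.

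Interferon-stimulated genes rose in both lines. RNA from leukocytes was not borne out as the source, since 6 genes abundant in leukocytes summed to at most 0.173 CPM in a TMZ library. That set was narrowed after a first set of 10 decided nothing, with CSF1R giving 121 counts over the libraries. In KO2 the first set stood at 2.61 and 2.21 CPM after TMZ against 0.977 and 0.745 CPM in control libraries. CSF1R gave 32 and 29 of the 41 and 36 counts in the KO2 TMZ libraries. In KO1 the first set showed no consistent rise, with 0.808 and 1.21 CPM after TMZ against 1.81 and 0.903 CPM in control libraries. The narrower test was set on values already seen, so it does not exclude this source. Scaling was excluded, since the lowest median over 5 scalings and both lines was 2.79. Transcription of interferon genes in the cells remains undecided: 10 interferon genes had at least 17 counts in each TMZ library but were not higher in CPM in every TMZ library than in the controls of its line, and IFNE gave 180 of the counts, while IFNB1 went from 0 and 1 to 17 and 7 counts in KO1 and from 0 and 0 to 2 and 2 in KO2.

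Immediate early genes fell in both lines. Scaling was excluded, since the highest median over 5 scalings and both lines was -1.11. A brief stimulus of the control cells before harvest, such as a change of medium, remains a possible explanation. The prediction that the more slowly changing ERK feedback genes would not fall was met, with medians of 0.541 in KO1 and 0.28 in KO2. They rose in KO1 (8 of 12 higher, 2 lower, camera adjusted p = 0.0051, adjusted p = 0.12 with an estimated correlation). In KO2 they did not pass (5 higher, 3 lower, camera adjusted p = 0.23). The prediction set no upper bound and would also be met if TMZ lowered immediate early genes alone, so this test cannot decide. Less transcription of short-lived RNAs as a class remains undecided, with medians of -0.300 in KO1 and -0.21 in KO2. The values depend on scaling: by the total count they were -0.129 and -0.01, above the bound of -0.25 set in advance for excluding it, and by the upper quartile -0.352 and -0.20. An effect of TMZ itself therefore stays as 1 explanation among others.

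TMZ lesions could block transcription along long genes, so a fall of long genes was tested. The higher of the partial rho values of the log2 change with genomic span was 0.0716, and with exonic length 0.0605, so neither loss with distance nor exonic length was borne out. The largest absolute partial rho with span between replicates of a group was 0.0576. These tests used 15533 of the 15850 genes.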

How the results depend on the processing

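Requiring at least 2-fold left 2003, 2432, 1588, 539 and 1475 genes in the averaged, KO1, KO2, difference and control comparisons, fewer by construction, and an adjusted p under 0.01 left 1129 for the difference. Leaving out 1 library gave 1192 to 3644 genes for the difference, where the lone sample is assumed to vary like the other groups. The counts of the other comparisons stayed within 1.5 times under every other alternative run. With only the 4 libraries compared, 8946 genes were called in KO1 against 7968 in the main fit. In KO2 the numbers were 5320 against 6560, and between control cells 4380 against 5402. The correlation between the lines was 0.203 with no filter on low counts, 0.712 with at least 1 CPM in 4 libraries and 0.505 to 0.556 with 1 library left out. With 1 library left out the filter was redone and was looser, since it follows the smallest group. How far the filter accounts for the change was not tested. Of 60 list calls 7 were kept with an estimated correlation. Fry made 108 calls and kept 58 of the 60. For the averaged effect it kept all 11, but it called 26 of the 29 lists tested there. The replicate block gave 9396, 8315, 7034, 2949 and 5867 genes, a correlation of 0.634 and 65 lists. The numbers do not pair the samples, as correlations between residuals ran from -0.003 to 0.069. Signs reversed when 1 library was left out in RSAD2, called in the difference (1.34 without KO2_control replicate 2), and in uncalled genes, and the cause was not tested: MKI67 in the difference (-0.147 to 0.0291), PPP2R2D (-0.00692 to 0.0807), JAKMIP3 (-0.601 to 0.265) and LRRC27 (-0.105 to 0.00520) between control cells. The 382 pairs of gene and comparison followed here came from the naming rule, which picks large changes and small p-values in these same data. High retention is therefore partly built in, and a gene called in neither fit also counts as kept. Other alternatives kept the call of single genes in 4001 cases, weakened it in 23 and strengthened it in 7. Leaving out a library kept it in 2955, weakened it in 92 and strengthened it in 5. MGMT had at most 14 counts per library.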

Other observations

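The lists in this part were chosen after the main results were seen, so their results are hypotheses. For the ERK feedback and short-lived lists, what their medians in each line should show was written before those medians were seen, as was the prediction for other splits of the libraries. Camera adjusted the 6 lists tested here over those 6. Enzymes of fatty acid synthesis, which SREBP factors drive with sterol synthesis and which hold SCD, fell in KO1 (0 of 16 higher, 11 lower, median -0.65, camera adjusted p = 9.1e-07, adjusted p = 0.016 with an estimated correlation). They did not pass in KO2 (4 higher, 7 lower, median -0.30, camera adjusted p = 0.084), where scaling by the total count gave 6 higher and 5 lower (median -0.10). For the averaged effect they were lower (2 higher, 11 lower, median -0.42, camera adjusted p = 0.00017, adjusted p = 0.041 with an estimated correlation). The difference between the lines passed (10 higher, 0 lower, median 0.50132, camera adjusted p = 5.1e-10, adjusted p = 0.013 with an estimated correlation). In control cells they were lower in KO2 (0 higher, 10 lower, median -0.45, camera adjusted p = 9.0e-05, adjusted p = 0.058 with an estimated correlation). The immediate early genes that FOS belongs to had 15 of 20 lower and 2 higher for the averaged effect (median -1.24, camera adjusted p = 7.9e-07, adjusted p = 0.027 with an estimated correlation).

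For the averaged effect, cytosolic tRNA synthetases, many of them ATF4 targets, rose in 15 of 20 cases and fell in 2 (median 0.31, camera adjusted p = 1.6e-05, adjusted p = 0.19 with an estimated correlation). Their difference between the lines passed (0 higher, 6 lower, median -0.26, camera adjusted p = 0.00012, adjusted p = 0.19 with an estimated correlation). Serine, glycine and folate enzymes rose in 8 of 11 cases and fell in 1 (median 0.53, camera adjusted p = 0.0016, adjusted p = 0.19 with an estimated correlation). They also differed between the lines (0 higher, 5 lower, median -0.29, camera adjusted p = 0.0022, adjusted p = 0.19 with an estimated correlation). ERK feedback genes rose in 8 of 12 cases and fell in 3 (median 0.41, camera adjusted p = 0.044, adjusted p = 0.22 with an estimated correlation). In KO2 alone they did not pass (5 higher, 3 lower, camera adjusted p = 0.23). Their difference between the lines passed (0 higher, 5 lower, median -0.37, camera adjusted p = 4.3e-05, adjusted p = 0.087 with an estimated correlation). Other genes with short-lived RNAs did not pass (5 of 16 higher, 8 lower, median -0.13, camera adjusted p = 0.27). Scaling by the total count turned the short-lived list to 8 higher and 7 lower (median 0.0533). Several members of these lists are also in the stress response list.

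A 2-group edgeR fit called 4639 genes between TMZ and control libraries, and 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many. The highest of the other splits, KO1 against KO2, called 1723 genes. Of the 35 splits, 32 part the replicates of a group and called 0 genes each, so only 3 splits of whole groups can be compared, too few for a share under 0.05. MALAT1, a nuclear noncoding RNA, changed by -1.73 ± 0.13, with 5070 ± 2188 CPM in the KO2 control libraries, and NEAT1, another, by -1.30 ± 0.06 for the averaged effect, while RN7SL2, of the signal recognition particle, changed by 1.15 ± 0.41.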
